A study of Ovis aries with 18 samples.

How the data were processed

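MicroRNAs (miRNAs), short RNAs that silence messenger RNAs and circulate in plasma inside vesicles and protein complexes, were sequenced from the plasma of Polish Longwool ewes. Per the labels' protocols, 12 ovariectomized ewes carrying estradiol implants were assigned to a standard diet (CTRL, 6 ewes) or a high-fat diet (OBESE, 6 ewes), blood was drawn at weeks 7, 10 and 14, and RNA was taken from 200 µL of plasma. The series holds 18 libraries in 6 groups of diet and week, with 3 replicates per group. The labels do not say whether a library is 1 ewe or a pool, or which ewes stand behind a replicate number. All p-values therefore measure the spread between these libraries, part of which may be technical, and libraries of 1 diet at different weeks may share ewes.

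Libraries were made with the QIAseq miRNA kit, which tags each molecule with a molecular identifier before amplification, and were read on an AVITI instrument as single reads of 76 nucleotides, per the labels' protocols. The submitters' processing notes name cutadapt 4.9, Bowtie 1.3.1 and DESeq2 1.42 without roles. The genome build, the miRNA annotation and the way reads matching several miRNAs were assigned are not given in the sources used here. The deposited values are raw counts per miRNA, whole numbers with a different total in each library. The library protocol states deduplication by molecular identifiers, but whether the counts are molecules or reads is not stated in the files. Each library has its own count file, and the authors also deposited a table of the same counts for the whole series. The table and the files differed in 0 values, and 0 columns of the table were left unmapped.

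The files list 364 features. Of these, 107 carry a miRNA name and 257 carry an identifier made of a word marking them as new and a running number. The latter are written here as "unnamed miRNA" with that running number, which is a description and not the identifier of the files. They come with no sequence, so nothing can be said of what they are, and some may be copies of a named miRNA. All 107 named features matched a miRNA gene by its synonyms in the RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0. Since the build of the files is not given, no coordinates are printed, and that table served only for names and neighbours.

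Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 168 features, 54 named and 114 unnamed. The 196 features left out held between 0.0311% and 0.0614% of a library's counts. Libraries were scaled by TMM, with factors from 0.653 to 1.19. One quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 18 libraries with 6 groups, which share 1 estimate of the spread (common dispersion 0.153, 12 residual degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment over the 168 features and a threshold of 0.05. The comparisons were OBESE against CTRL at each of the 3 weeks, the mean of these 3 differences, weeks 10 and 14 against week 7 within each diet, and the interaction of diet and week. Fold changes are log2 with standard errors (SE), and 95% intervals use the moderated degrees of freedom. For edgeR the SE was derived from the test, as the size of the log2 fold change divided by the square root of its F statistic. It is therefore approximate, above all for features near 0 counts. Levels are CPM, counts divided by the library total as scaled by TMM, computed here from the deposited counts and given as mean ± SD.

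Of 15 miRNA lists fixed in advance, 10 had at least 3 tested members. They were tested in limma 3.58.1 with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members were also adjusted over the list alone. Library measures were compared by exact permutation of diet labels within weeks (8000 assignments), and a comparison of 3 libraries against 3 cannot give a two-sided p below 0.1. The miRNAs named in the text are, by a rule set beforehand, the 10 most abundant, those past the threshold or otherwise the 10 smallest p for each diet comparison and the 5 smallest p for each week comparison and the interaction, and the 2 to 4 members with the smallest p of each tested list. The comparisons, tests, lists, naming rule and all alternatives but those named below as added were fixed before the data were examined.

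The edgeR step was tested on simulated counts for the 168 features, drawn from the measured means, library sizes and dispersions with 40 features changed. For the diet comparison at week 7 it recovered 35% of 2-fold and 73% of 4-fold changes, with 4% false calls. For the diet difference averaged over weeks, with all libraries drawn independently, it recovered 71.8% and 96.2%, with 4% false calls. Both simulations changed 20 features 2-fold and 20 features 4-fold. With fewer changed features the adjusted threshold is harder to pass, so recovery may be lower, which was not simulated. In simulations of the latter comparison with no change, 1 of 20 gave a call. The list test gave p under 0.05 in 100% of shifted and 5% of unshifted lists of 10 features in the averaged comparison. The members of these lists were picked at random and drawn independently. The 5% therefore does not cover lists with correlated members, such as the DLK1-DIO3 list with an estimated correlation of 0.317.

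Total counts ranged from 388574 to 1269829 per library. A count of 0 allows a level of up to 3 counts, which is between 2.36 and 7.72 CPM of the unscaled total depending on the library. Such floors cover counting error only. Replicates within groups differed by far more than counting noise, with chi-square per degree of freedom from 29.6 to 541, so no library was counted as a second reading of another, while repeat preparations from 1 plasma sample would exceed counting noise too and are not excluded.

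Whether replicate numbers pair libraries was checked through the correlation of deviations from group means over the 168 features. Within diets, all 3 same-number pairs exceeded 0.1 for CTRL weeks 7 and 10 (0.29 to 0.41), CTRL weeks 10 and 14 (0.36 to 0.50), OBESE weeks 7 and 14 (0.11 to 0.42) and OBESE weeks 10 and 14 (0.45 to 0.69). They did not for CTRL weeks 7 and 14 (lowest 0.014) or OBESE weeks 7 and 10 (lowest -0.025), nor between diets at any week. By this rule the numbers were taken to pair CTRL weeks 10 and 7 and OBESE weeks 14 and 7. A number that marked 1 ewe would do so at all 3 weeks, so the rule does not settle the pairing. The blocked fit was computed for all week comparisons as an alternative, and their main values come from the fit without blocks.

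Alternatives were RLE size factors, no TMM factor, no filter, at least 10 counts in every library, DESeq2 1.42.0, limma-voom, leaving out each library, the series-wide table, only the 6 libraries compared, replicate blocks, counts summed over weeks, a correlation between weeks and a covariate for red blood cell miRNAs. Counting near-identical features once, leaving out both libraries with the lowest TMM factors, leaving out each library in the list tests and the mean log2 CPM of the red blood cell list as a library measure were added after seeing the data. Near-identical features, whose counts differed by under 3% on average, form sets of unnamed miRNAs that may share reads (8 and 9, 38, 40 and 41, 45 and 46, 54 and 80, 87 and 88, 220, 225 and 238, and 223 and 229). Related named miRNAs differ by few bases, so the division of counts among them is uncertain. Examples are the let-7 members, miR-103 and miR-107, miR-26a and miR-26b, miR-23a and miR-23b, and miR-30a-5p and miR-30d.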

Results

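Plasma miRNAs were counted in ewes kept on a standard diet (CTRL) or on a high-fat diet (OBESE), in a study concerned with leptin resistance in obesity. Blood taken at weeks 7, 10 and 14 gave 3 libraries per diet and week. Total counts averaged 732300 ± 275000 in the CTRL libraries and 776400 ± 237000 in the OBESE libraries (SD, n = 9 each), and ranged from 388574 in CTRL week 10 replicate 1 to 1269829 in CTRL week 10 replicate 3. Between 222 and 292 of the 364 features had at least 1 count in a library.

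Sheep plasma was dominated by few miRNAs. miR-16b, a member of the miR-15/16 family that is abundant in blood cells, took 47.1% ± 3.54 of the counts (SD, n = 18). Unnamed miRNA 1 took 12.6% ± 3.49 and unnamed miRNA 2 took 11.9% ± 2.11. The let-7 family, regulators of growth and metabolism, followed with let-7b at 4.25% ± 0.908, let-7g at 3.92% ± 0.668 and let-7a at 2.70% ± 0.442. The remaining members of the 10 most abundant were miR-191 (3.48% ± 0.899), unnamed miRNA 3 (1.79% ± 0.46), miR-30d (1.03% ± 0.31) and unnamed miRNA 4 (0.915% ± 0.23). These 10 together held 89.8% of the counts, and the 7 let-7 members together held 12.7% ± 1.93.

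**Figure D1:**
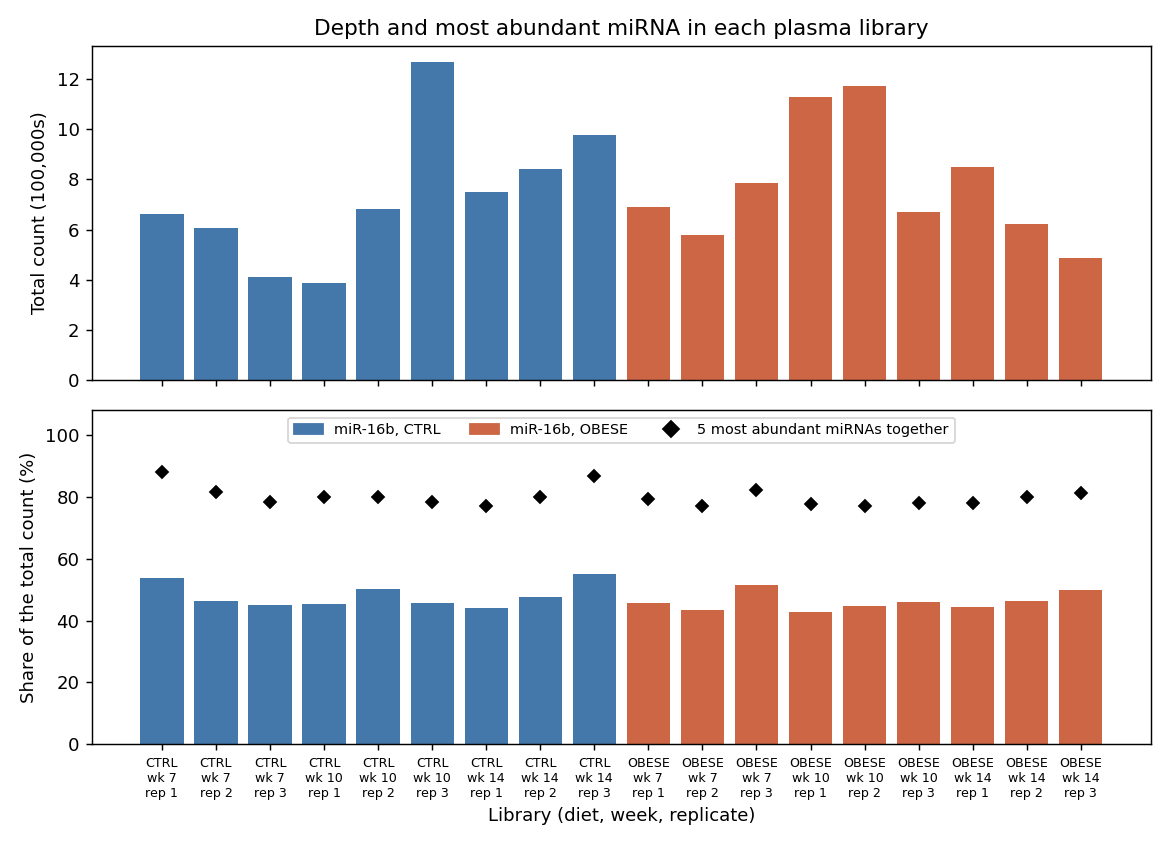
Total count per library (upper bars, from 388574 to 1269829 counts) and share of the total taken by miR-16b (lower bars, %) and by the 5 most abundant miRNAs (diamonds, %), for each of the 18 libraries by diet, week and replicate. miR-16b took between 42.7% and 55.1% of the counts, with its highest shares in CTRL week 14 replicate 3 and CTRL week 7 replicate 1.

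None of 5 measures of depth and composition passed a test between the diets. A measure of the 3 counted members of the red blood cell list, added to them (exact p = 0.0482, unadjusted), is given with that list below. The share of miR-16b was 48.15% ± 4.01 in CTRL and 46.13% ± 2.86 in OBESE libraries (SD, n = 9 each; two-sided exact permutation within weeks, p = 0.25). The 5 most abundant miRNAs took 81.1% ± 3.8 and 79.02% ± 1.87 (exact p = 0.166). Features with at least 1 count numbered 252.8 ± 18.5 and 263.1 ± 14.7 (exact p = 0.174), and those with at least 10 counts 150.6 ± 14.2 and 157.8 ± 9.72 (exact p = 0.217). Total counts gave an exact p of 0.718, and over these 5 measures the smallest Benjamini-Hochberg adjusted exact p was 0.312. Within single weeks the smallest exact p was 0.1, the lowest that 3 libraries against 3 can give. It was reached where the diets did not overlap. At week 7, features with at least 1 count numbered 257 to 266 in OBESE and 222 to 243 in CTRL libraries. Those with at least 10 counts numbered 149 to 159 and 129 to 147. At week 10, the 5 most abundant miRNAs took 76.96% to 78.18% in OBESE and 78.35% to 80.12% in CTRL libraries. CTRL week 7 replicate 1 and CTRL week 14 replicate 3 stood apart from the rest, with TMM factors of 0.653 and 0.718, miR-16b shares of 53.92% and 55.08%, and 87.97% and 86.7% of counts in their top 5 miRNAs.

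The first question was whether plasma miRNAs differed between the diets over the whole period. Averaged over the 3 weeks, miR-30a-5p, a member of the miR-30 family studied in fat cell differentiation, stood at 2620 ± 735 CPM in OBESE and 1640 ± 373 CPM in CTRL libraries (SD, n = 9 each). Its fitted log2 fold change was 0.67 (SE 0.175), positive in all 3 weeks. miR-17-5p, from the growth-promoting miR-17/92 clusters, stood at 453 ± 107 CPM in OBESE and 630 ± 192 CPM in CTRL libraries, a log2 fold change of -0.50 (SE 0.15), with the negative sign in 2 of 3 weeks. miR-323c, encoded in the imprinted DLK1-DIO3 locus, stood at 52.9 ± 26.8 and 25.1 ± 17.2 CPM, a log2 fold change of 1.07 (SE 0.352). None of these passed the test once adjusted over the 168 features.

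With edgeR, 0 of 168 miRNAs passed an adjusted p of 0.05 for this averaged difference, while 19 had an unadjusted p under 0.05, 10 of them higher and 9 lower in OBESE, against 8.4 expected by chance. The 19 count the near-identical unnamed miRNAs 8 and 9, 45 and 46, and 223 and 229 separately, and the 168 hold such copies too. limma-voom gave 0 and 20. DESeq2, which was run on all 364 features, gave 2 and 27. Its calls were miR-30a-5p and unnamed miRNA 22, each at a DESeq2 adjusted p of 0.0419 (over all alternatives 0.0212 to 0.656 and 0.0212 to 0.655). Without the filter on low counts, edgeR tested 364 features and gave 4 calls and 29 at an unadjusted p under 0.05. The smallest edgeR adjusted p in the filtered set was 0.113, for miR-30a-5p and for unnamed miRNA 22, which stood at 1210 ± 266 CPM in OBESE and 848 ± 146 CPM in CTRL libraries (log2 fold change 0.50, SE 0.125). The median 95% interval reached 0.532 on the log2 scale to either side of its estimate. Since libraries of 1 diet at different weeks may come from the same ewes, these p-values may be too small. With counts summed over weeks into 3 values per diet, edgeR gave 0 calls, 13 at an unadjusted p under 0.05, and a smallest adjusted p of 0.465. Leaving out 1 library gave edgeR calls in 3 of 18 fits, unnamed miRNA 27 without OBESE week 7 replicate 2 (adjusted p = 0.0194), miR-30a-5p and unnamed miRNA 22 without OBESE week 10 replicate 1 (0.0212 each) and miR-17-5p without CTRL week 14 replicate 2 (0.0486).

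Among the other features with the smallest p, unnamed miRNA 27 had a log2 fold change of -2.69 (SE 0.809, edgeR adjusted p = 0.167). Its libraries fell into separate levels that cut across the diets. It lay between 1140 and 3610 CPM in 7 libraries, which were CTRL replicates 1 and 2 at each week and OBESE week 7 replicate 2, and between 64.9 and 142 CPM in the other 11. The near-identical unnamed miRNAs 45 and 46 had log2 fold changes of 1.61 (SE 0.563) and 1.63 (SE 0.567), and unnamed miRNA 45 was highest in OBESE replicate 3, at 263, 273 and 373 CPM at weeks 7, 10 and 14. Over all alternatives their log2 fold changes ranged from 0.798 to 1.86 and from 0.811 to 1.88. The edgeR, DESeq2 or limma adjusted p ranged from 0.0339 to 0.728 for each. The near-identical unnamed miRNAs 223 and 229 both had a log2 fold change of 0.55 (SE 0.195), and unnamed miRNA 35 had 0.35 (SE 0.126). The edgeR adjusted p of these 5 features was 0.202, and none passed.

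**Figure D2:**
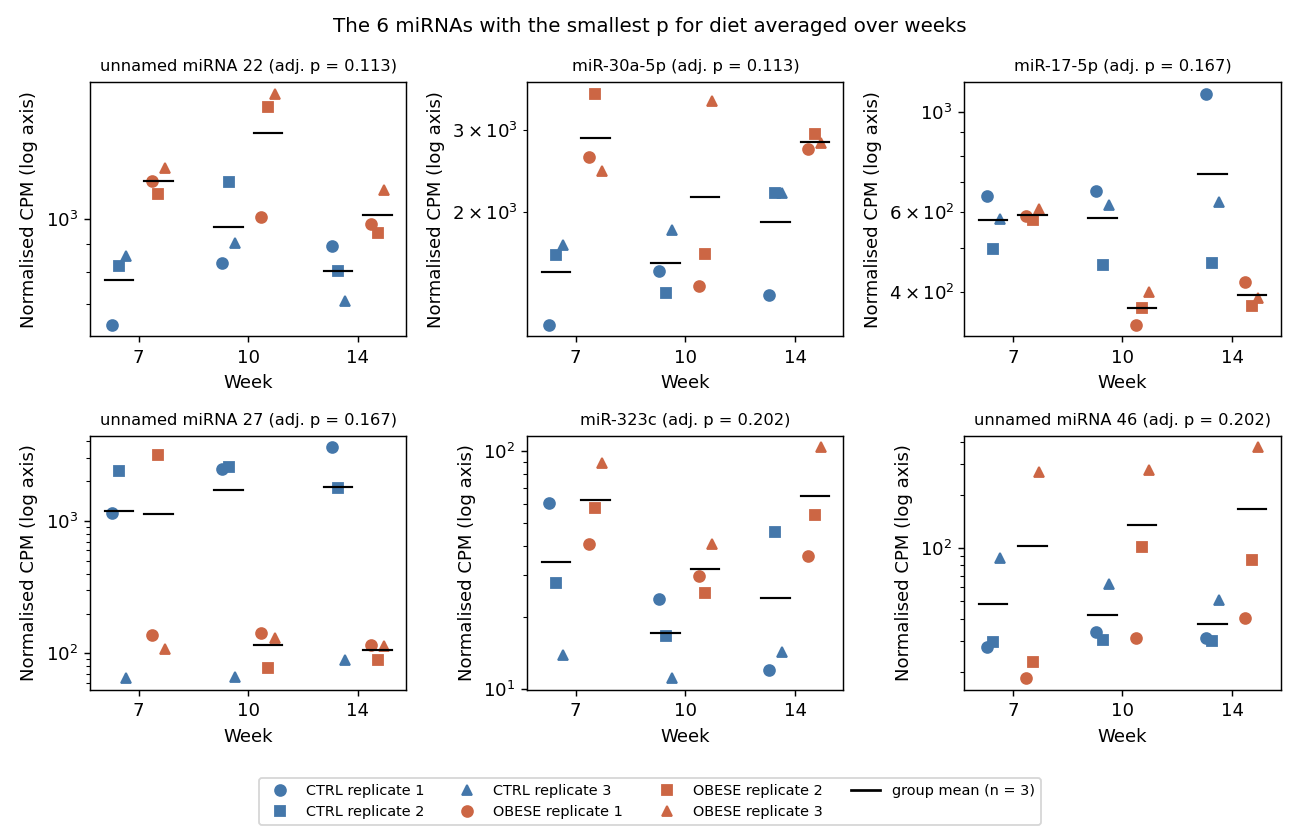
Levels of the 6 miRNAs with the smallest p for the diet difference averaged over weeks, as normalised CPM on log axes, by week (7, 10, 14), with 1 symbol per library (blue CTRL, orange OBESE, symbol shape for the replicate number) and lines for group means (n = 3). miR-30a-5p averaged 2620 CPM in OBESE and 1640 CPM in CTRL libraries with overlapping values, while unnamed miRNA 27 sits at 1142 CPM or more in 7 libraries and at 142.4 CPM or less in the other 11.

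The fixed miRNA lists were compared between diets over the same averaged difference. The 3 tested members of the miR-17/92 clusters had negative log2 fold changes, miR-17-5p of -0.50, miR-106b of -0.40 (SE 0.192) and miR-25 of -0.21 (SE 0.175), with a median of -0.40, while without TMM scaling 1 of the 3 (miR-25) was positive and the median was -0.22, and miR-25 had 0.05 (SE 0.143) without both libraries with low TMM factors. The camera test of limma gave an adjusted p of 0.107 for this list over the 10 lists, and an adjusted p = 0.477 with an estimated correlation. Of the 18 fits that left out 1 library, an alternative added after the data were seen, it passed camera at the preset correlation in 1, without CTRL week 14 replicate 2 (adjusted p = 0.0257). The red blood cell list shares miR-106b and miR-25 with it and adds miR-16b at -0.28 (SE 0.149), so that its 3 members were negative (1 of 3 positive without TMM scaling), with a camera adjusted p of 0.23. The files held no named feature for the other miRNAs fixed for the red blood cell list, among them miR-451, miR-486 and miR-144. Its values therefore rest on these 3 members alone. Dropping the TMM factor placed the median over all 168 features at 0.16 for this difference, at 0.25 and 0.15 for the diets at weeks 7 and 14 and at 0.14 for CTRL week 10 against week 7, where with TMM it lay between -0.07 and 0, so directions hold relative to the median miRNA. The mean log2 CPM of the red blood cell list was 12.31 ± 0.341 in CTRL and 12.04 ± 0.215 in OBESE libraries (SD, n = 9 each; two-sided exact permutation within weeks, p = 0.0482, unadjusted, for a measure added to the 5 above). Its mean was 12.15 in the 7 CTRL libraries left without the pair that stood apart. The exact p treats the weeks as independent, so it may be too small where libraries of 1 diet share ewes.

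In the DLK1-DIO3 list, 56 named features of 41 RefSeq genes on 1 chromosome, 14 were tested, 9 with positive and 5 with negative log2 fold changes and a median of 0.25 (12 positive, 2 negative and a median of 0.47 without TMM scaling). miR-323c was followed by miR-409-3p at 0.51 (SE 0.208), miR-382-5p at 0.38 (SE 0.24) and miR-376b-3p at -0.91 (SE 0.597), and the list's camera adjusted p was 0.261, and 0.68 with an estimated correlation of 0.317 between members. Among the 18 fits without 1 library, which were run at the preset correlation alone, it passed in 1, without CTRL week 7 replicate 1 (adjusted p = 0.015). In the miR-30 family miR-30a-5p stood alone at 0.67, with miR-30a-3p at 0.10 (SE 0.139), miR-30b at -0.12 (SE 0.285) and a list median of 0.04 (0.20 without TMM scaling). The related miR-30d had 0.04 (SE 0.154), at 10200 ± 1640 CPM in OBESE and 10000 ± 3380 CPM in CTRL libraries. Whether the division of reads between miR-30d and miR-30a-5p affects the latter was not tested. In the adipose and insulin list, which also holds miR-30a-5p, 7 of 10 members were positive (10 of 10 without TMM scaling), with miR-26a at 0.32 (SE 0.132) and miR-221 at -0.06 (SE 0.146). The camera adjusted p was 0.32 for both of these lists. In the let-7 family 6 of 7 members were negative and 1 positive, let-7g at -0.21 (SE 0.105), let-7i at -0.14 (SE 0.0955) and let-7c at -0.16 (SE 0.131), while without TMM scaling 6 of 7 were positive. The camera adjusted p of the let-7 family was 0.32.

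The remaining lists had medians between -0.00331 and 0.11. Among miRNAs abundant in platelets, miR-199a-3p had 0.17 (SE 0.145) and miR-191 had 0.06 (SE 0.129), with a camera adjusted p of 0.734. The inflammation list, with miR-221 and miR-125b at 0.04 (SE 0.209), had an adjusted p of 0.851, as had the miR-23/27/24 clusters (median 0.04, mean -0.04), with miR-23b at -0.32 (SE 0.219) and miR-23a at 0.17 (SE 0.147). In the family of miR-10a, miR-10b, miR-99a and miR-125b, miR-99a had 0.25 (SE 0.19) and miR-10b had 0.18 (SE 0.147), with an adjusted p of 0.592. Adjusted over all 168 features, 0 members of any list passed with edgeR. Adjusted over the list alone, 1 member passed in the miR-30 family (miR-30a-5p, edgeR adjusted p = 0.00675), 1 in the adipose and insulin list (miR-30a-5p, 0.0135), 1 in the miR-17/92 clusters (miR-17-5p, 0.0116) and 0 in each of the other 7. fry gave a smallest adjusted p of 0.111, for the miR-17/92 clusters.

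**Figure D3:**
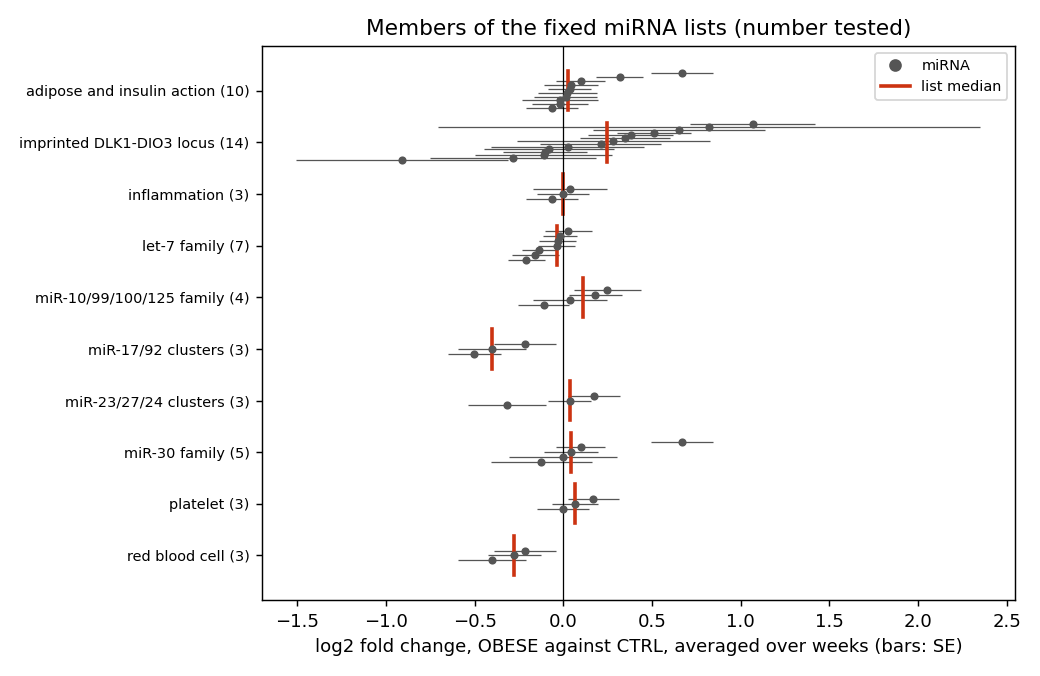
log2 fold changes of OBESE against CTRL averaged over weeks (points, with SE bars) for the members of the 10 fixed miRNA lists, with list medians as red lines and the number of tested members in parentheses. The miR-17/92 and red blood cell lists lie below 0 with medians of -0.40 and -0.28, where without TMM scaling 1 of 3 members of each lies above 0, and the DLK1-DIO3 list spreads from -0.91 to 1.07.

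The diets were next compared at each week. At week 7, miR-30a-5p stood at 2880 ± 612 CPM in OBESE and 1480 ± 298 CPM in CTRL libraries (SD, n = 3 each), a log2 fold change of 0.96 (SE 0.304) with no overlap of the groups. miR-26b, a miRNA of the same adipose and insulin list, stood at 3240 ± 568 and 2080 ± 645 CPM, and miR-485-5p of the DLK1-DIO3 locus at 41.7 ± 13.6 and 79.3 ± 22.8 CPM. miR-133, known from muscle, averaged 14.3 ± 8.16 in OBESE and 56.6 ± 61.4 CPM in CTRL, the latter through 127.5 CPM in CTRL replicate 1. The unnamed miRNAs 47, 22, 34 and 91 had positive log2 fold changes between 0.60 and 2.38, and unnamed miRNAs 3 and 233 had -0.66 and -1.13. Unnamed miRNA 91 lay near the counting floor, at 14.5 and 2.33 CPM.

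None of these passed over all 168 miRNAs at week 7, while miR-30a-5p passed when adjusted over the miR-30 family alone (edgeR adjusted p = 0.0291). edgeR gave 0 calls among 168 miRNAs with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.382, DESeq2 gave 0 and 15, and limma-voom gave 0 and 10. The groups did not overlap for 15 of the 168 miRNAs, against a share of 10% by chance for 3 libraries against 3. In the list tests, camera gave adjusted p values of 0.155 for the miR-30 family, with 4 of 5 members positive, and 0.213 for the adipose and insulin list, with 8 of 10 positive, and 0 of 10 lists passed. The DLK1-DIO3 list had a median of 0.04 and a mean of -0.06, with 7 of 14 members positive (8 of 14 and a median of 0.35 without TMM scaling) and a camera adjusted p of 0.962.

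At week 10, miR-17-5p stood at 370 ± 30.4 CPM in OBESE and 584 ± 111 CPM in CTRL libraries (SD, n = 3 each), a log2 fold change of -0.66 (SE 0.26). miR-29a, a regulator of collagen and of insulin signalling, stood at 5670 ± 584 and 3850 ± 481 CPM, a log2 fold change of 0.56 (SE 0.231). Neither overlapped between groups. Unnamed miRNA 35 had the smallest p, at 638 ± 74.9 and 406 ± 53.1 CPM (log2 fold change 0.65, SE 0.219), and unnamed miRNA 22 had 0.57 (SE 0.216). Unnamed miRNA 27 had -3.87 (SE 1.47), and unnamed miRNAs 43, 233, 6, 15 and 18 had log2 fold changes between -0.93 and -0.43.

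edgeR gave 0 calls at week 10 with 11 miRNAs at an unadjusted p under 0.05 and a smallest adjusted p of 0.643, DESeq2 gave 0 and 16, and limma-voom gave 0 and 13. The groups did not overlap for 22 of 168 miRNAs, against the 10% that chance gives. The 3 members of the miR-17/92 clusters were negative (1 of 3 positive without TMM scaling), with a median of -0.53 and a camera adjusted p of 0.263, and 0 of 10 lists passed.

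At week 14, the end of the diet period, miR-17-5p stood at 395 ± 24.8 CPM in OBESE and 730 ± 326 CPM in CTRL libraries (SD, n = 3 each), a log2 fold change of -0.88 (SE 0.261), with CTRL replicate 1 at 1094 CPM. miR-30b stood at 20 ± 8.74 and 58.7 ± 30.2 CPM, a log2 fold change of -1.51 (SE 0.502). miR-323c stood at 64.5 ± 35 and 24 ± 18.9 CPM (1.40, SE 0.602) and miR-485-5p at 73.7 ± 14.4 and 39.2 ± 9.67 CPM (0.90, SE 0.415). Unnamed miRNAs 57, 223, 229 and 28 had log2 fold changes between 0.73 and 0.95, and unnamed miRNA 27 had -4.11 (SE 1.5). Unnamed miRNA 111 stood at 18.5 ± 12.3 and 1.75 ± 1.53 CPM, the latter below the floor of these libraries.

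edgeR gave 0 calls at week 14 with 13 miRNAs at an unadjusted p under 0.05, 10 of them higher in OBESE, and a smallest adjusted p of 0.319. DESeq2 gave 0 and 15, and limma-voom gave 0 and 13. Leaving out CTRL replicate 2 brought miR-17-5p to a log2 fold change of -1.15 (SE 0.24) and an edgeR adjusted p of 0.0309, the 1 call among the fits that left out a library at this week (over all alternatives the adjusted p ranged from 0.0309 to 0.768). Without CTRL replicate 1 its log2 fold change was -0.49. The groups did not overlap for 16 of 168 miRNAs, against 10% by chance. Adjusted over the list alone, miR-17-5p passed in the miR-17/92 clusters (edgeR adjusted p = 0.0103) and 1 member, miR-30b, in the miR-30 family (0.039).

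Of the 10 lists, the DLK1-DIO3 miRNAs, which are transcribed from the maternal copy of an imprinted locus, passed camera at week 14, with 11 of 14 members positive, a median log2 fold change of 0.73 and an adjusted p of 0.0258. The call was lost with an estimated correlation of 0.317 between members (adjusted p = 0.69), and fry, which does not compare a list with other miRNAs, gave an adjusted p of 0.588. It was also lost without CTRL replicate 1 (camera adjusted p = 0.345), CTRL replicate 3 (0.107), OBESE replicate 1 (0.0522) or OBESE replicate 3 (0.411), and held without CTRL replicate 2 (0.0106, with the miR-17/92 clusters passing at 0.022) or OBESE replicate 2 (0.000509), each at the preset correlation. It was lost as well without both libraries with low TMM factors (adjusted p = 0.2). No member passed by itself over all 168 miRNAs.

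Within the CTRL diet, weeks 10 and 14 were set against week 7 to see how plasma miRNAs moved with time alone. miR-133 averaged 8.27 ± 5.14 CPM at week 10 and 56.6 ± 61.4 CPM at week 7 (SD, n = 3 each), and unnamed miRNA 34 averaged 691 ± 257 and 400 ± 85.7 CPM. Unnamed miRNA 68 averaged 16.7 ± 12.8 and 39.5 ± 10.7 CPM, and unnamed miRNA 3 averaged 16600 ± 1360 and 22000 ± 3430 CPM. Unnamed miRNA 245 had 0 counts in the week 10 libraries, which allows up to 2.36 to 7.72 CPM, and stood at 34.76, 3.489 and 0 CPM in those of week 7. With edgeR 0 miRNAs passed and 3 had an unadjusted p under 0.05 (smallest adjusted p 0.947). DESeq2 gave 0 and 5, and limma-voom gave 0 and 3. For 8 of 168 miRNAs the groups did not overlap, against 10% by chance.

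At week 14 against week 7 of the CTRL diet, miR-485-5p averaged 39.2 ± 9.67 and 79.3 ± 22.8 CPM, and miR-30b 58.7 ± 30.2 and 26.9 ± 10.7 CPM (SD, n = 3 each). Unnamed miRNA 30 averaged 445 ± 12.6 and 667 ± 76.1 CPM, and unnamed miRNA 81 averaged 34.5 ± 13.9 and 16.2 ± 2.29 CPM. miR-3957-5p had 0 counts in the 3 week 7 libraries, which allows up to 4.54 to 7.28 CPM, and was counted in 1 week 14 library, at 62.3 CPM. edgeR gave 0 calls and 6 miRNAs at an unadjusted p under 0.05 (smallest adjusted p 0.963), DESeq2 gave 0 and 7, and limma-voom gave 0 and 5. For 9 of 168 miRNAs the groups did not overlap, against 10% by chance.

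Within the OBESE diet, miR-17-5p averaged 370 ± 30.4 CPM at week 10 and 592 ± 17.5 CPM at week 7 (SD, n = 3 each; log2 fold change -0.68, SE 0.26), and miR-106b of the same clusters averaged 103 ± 20.9 and 179 ± 9.53 CPM (log2 fold change -0.79, SE 0.333). miR-29a averaged 5670 ± 584 and 3810 ± 539 CPM, and unnamed miRNA 13 averaged 1770 ± 668 and 1000 ± 115 CPM. Unnamed miRNA 27 had a log2 fold change of -3.28, which rested on OBESE week 7 replicate 2 and was 0.07 (SE 1.24) without it. edgeR gave 0 calls and 7 miRNAs at an unadjusted p under 0.05 (smallest adjusted p 0.897), DESeq2 gave 0 and 8, and limma-voom gave 0 and 6. The groups did not overlap for 27 of 168 miRNAs, against 10% by chance.

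At week 14 against week 7 of the OBESE diet, unnamed miRNA 233 averaged 110 ± 48.1 and 46.4 ± 14 CPM (SD, n = 3 each; log2 fold change 1.24, SE 0.383), and unnamed miRNA 223 averaged 324 ± 56.4 and 168 ± 25.6 CPM. Unnamed miRNA 93 averaged 5.71 ± 2.26 and 21.4 ± 9.48 CPM. Unnamed miRNA 111 averaged 18.5 ± 12.3 and 0.438 ± 0.759 CPM and miR-3957-5p 34.9 ± 41.8 and 0.438 ± 0.759 CPM, so that both lay below the floor at week 7. edgeR gave 0 calls and 13 miRNAs at an unadjusted p under 0.05 (smallest adjusted p 0.341), DESeq2 gave 0 and 15, and limma-voom gave 0 and 12. The groups did not overlap for 23 of 168 miRNAs, against 10% by chance.

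The last question was whether the diet difference changed over the weeks. miR-30b had the smallest p for the interaction, with log2 fold changes of OBESE against CTRL of 0.70 (SE 0.509) at week 7, 0.44 (SE 0.481) at week 10 and -1.51 (SE 0.502) at week 14. miR-485-5p went from -0.93 (SE 0.418) at week 7 to 0.90 (SE 0.415) at week 14, and miR-26b from 0.64 (SE 0.276) to -0.35 (SE 0.275). Unnamed miRNA 3 went from -0.66 (SE 0.218) to 0.29 (SE 0.218), and unnamed miRNA 111 lay near the floor. None of these differences between weeks passed. edgeR gave 0 calls and 7 miRNAs at an unadjusted p under 0.05 (smallest adjusted p 0.833), the likelihood ratio test of DESeq2 gave 0 and 13, and limma-voom gave 0 and 7.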

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

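The tests of explanations for unnamed miRNA 27 described here were chosen after its values were seen. Within the 9 libraries of each diet, 50 sets of values were screened for a single library far from the others (5 library measures, and log2 CPM of the 10 most abundant miRNAs and of the 10 with the smallest p for diet averaged over weeks). Chance alone gives about 1 in 20, and 2 were found.

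miR-17-5p was highest in CTRL week 14 replicate 1, where the gap to the next library was 0.564 of the range of the 9 CTRL libraries, beyond the 95% critical value of Dixon's test for 9 values. That library held 1094 CPM and the next CTRL library 670.2 CPM.

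Unnamed miRNA 27 was highest in OBESE week 7 replicate 2, where the gap was 0.836 of the range of the 9 OBESE libraries. That library held 2073 counts (3140 CPM), and the libraries with the same number at weeks 10 and 14 held 91 and 55 counts. A lowering by the high-fat diet alike in every ewe cannot be told apart from differences between ewes: 3 CTRL libraries lay among the low libraries at 64.9, 65.7 and 89.8 CPM, but they share replicate number 3, and 1 ewe with a low level of its own does not forbid such a lowering in the others. A difference between individual ewes that is constant over time, such as a sequence variant, may account for 5 of the 6 combinations of diet and replicate number, which stayed on one side at all weeks, and cannot be told apart from other explanations while the labels do not tie libraries to ewes. A candidate explanation for the sixth is that the library labelled OBESE week 7 replicate 2 came from another ewe than those at weeks 10 and 14: with unnamed miRNA 27 left out, its mean correlation with its own later libraries was 0.076, the lowest of the 6 week 7 libraries (the others 0.14 to 0.42), and it was 0.24 with those of CTRL replicate 1. CTRL week 7 replicate 1 also correlated more with another combination (0.29 with OBESE replicate 1) than with its own, so this hint is weak.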

How the results depend on the processing

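The counts of 0 for all 9 comparisons held under RLE size factors, no TMM factor, at least 10 counts in every library, limma-voom, the series-wide table, only the 6 libraries compared, the red blood cell covariate, and, chosen after seeing the data, near-identical features counted once and both low-TMM libraries left out, where each was run. The diet difference averaged over weeks gave 4 calls without the filter (miR-30a-5p and unnamed miRNAs 27, 45 and 46) and 2 with DESeq2 (miR-30a-5p and unnamed miRNA 22), which changes the set of features and the model; the cause was not tested further. Leaving out each library gave 0 to 2 calls for it: 1 without OBESE week 7 replicate 2 (unnamed miRNA 27), 2 without OBESE week 10 replicate 1 (miR-30a-5p and unnamed miRNA 22) and 1 without CTRL week 14 replicate 2 (miR-17-5p). It gave 0 to 1 for the diets at week 14 and 0 for each of the other 7 comparisons. Over all alternatives the edgeR, DESeq2 or limma adjusted p for the averaged difference ranged from 0.0212 to 0.656 for miR-30a-5p and from 0.0486 to 0.656 for miR-17-5p, with log2 fold changes of 0.49 to 0.84 and -0.60 to -0.34.

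With the replicate block of diet and number, the comparisons between weeks and the interaction had 0 calls each, so it changed no call. The numbers were not taken to pair libraries across diets, though a part shared by them stays open (mean correlation 0.12); with the replicate block in the 6 libraries of a week, edgeR gave 0 calls at week 7, 1 at week 10 (unnamed miRNA 27, adjusted p 3.96e-05) and 2 at week 14 (unnamed miRNAs 27 and 244, 2.67e-10 and 0.0124), though for unnamed miRNA 27 OBESE was the higher in replicate 3 (130 against 65.7 CPM at week 10, 113 against 89.8 CPM at week 14), and the averaged difference had 0 with the block. Counts summed over weeks and limma-voom with a correlation of 0.22 between weeks gave 0.

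The DLK1-DIO3 list call at week 14 became 0 lists with an estimated correlation and 0 without both low-TMM libraries, and stayed 1 without TMM. Leaving out each library, chosen after seeing the data, gave 0 to 2 lists at week 14, 0 to 1 for the averaged difference (1 without CTRL week 7 replicate 1, DLK1-DIO3, and 1 without CTRL week 14 replicate 2, miR-17/92) and 0 at weeks 7 and 10. Among 1280 refitted values of the miRNAs named for their p in a comparison, 1 changed sign. The 1280 include adjusted p values for the interaction, which have no sign. The miRNAs were picked for a small p in these same data, which favours a stable sign. The change was in unnamed miRNA 27 at OBESE week 10 against week 7. Its value ranged from -3.73 without OBESE week 7 replicate 3 to 0.0657 without OBESE week 7 replicate 2. The cause was not tested further. Of 618 refitted values of the 20 further list members named for the averaged difference, 0 passed and 20 changed sign, in 9 members with log2 fold changes of up to 0.276 in size. Without TMM scaling, which raises the median of all features, these were miR-221 (0.111), let-7i (0.0385), let-7c (0.00661), miR-30b (0.0598) and miR-25 (0.0137). With the red blood cell covariate, which is the mean of a list that holds miR-25 and miR-16b, they were miR-25 (0.158), miR-16b (0.0133) and miR-30a-3p (-0.00932). miR-25 had 0.0503 without both low-TMM libraries, and miR-125b had -0.00683 with near-identical features counted once. Leaving out each library, miR-125b ranged from -0.103 to 0.112 and miR-191 from -0.0557 to 0.11; the cause of these changes was not tested further. miR-3957-5p gave no value at CTRL week 14 against week 7 without CTRL week 14 replicate 1, which left no count in either group. Depth limits miRNAs under about 7.72 CPM, where a library may hold no count at all.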

Other observations

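All tests in this part other than the counts of divisions and the thinning to equal depth were chosen after the values were seen. In a fit with the replicate number within each diet as a term, edgeR gave 15 of 168 miRNAs that differed between replicate numbers at an adjusted p under 0.05. Each comparison of diet or week gave 0 in the fit without this term. Those comparisons test fewer differences at a time and leave the variation between numbers in the error, so these counts cannot be set against each other. The 15 were miR-382-5p (edgeR adjusted p = 0.00561), miR-432 (0.0199), miR-3957-5p and miR-493-3p (0.0376 each), all from the imprinted DLK1-DIO3 locus, and 11 unnamed miRNAs led by 46 and 45 (6.33e-05 each) and 71 (0.000464). The 11 count 2 near-identical pairs (45 and 46, 54 and 80) as 2 miRNAs each. The locus was singled out from these same results, though its list was fixed in advance. Its tally was 4 of 14 tested members against 11 of the other 154 miRNAs (Fisher's exact test, p = 0.024). That test reuses the miRNAs that prompted it and takes members as independent, so it gives no support. The 4 members are also on the list as tested at week 14. There camera gave an adjusted p of 0.0258 at the preset correlation and 0.69 with an estimated correlation.

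miR-150, abundant in lymphocytes, reached 26790 CPM in OBESE week 10 replicate 2 and stood between 2364 and 12950 CPM in the other 17 libraries. Lists with fewer than 3 tested members were not tested as groups. Averaged over weeks, their log2 fold changes of OBESE against CTRL were 0.38 (SE 0.322) for miR-150 and 0.23 (SE 0.133) for miR-29a of the leukocyte list, and 0.45 (SE 0.265) for miR-194 and 0.20 (SE 0.456) for miR-148a of the liver list. They were 0.33 (SE 0.177) for miR-200c and 0.16 (SE 0.19) for miR-200a of the miR-200 family, and -0.51 (SE 0.515) for miR-133 of the muscle list, and miR-29a is also the 1 tested member of its own family. Among the 196 features left out of the tests, the highest count was 64, for unnamed miRNA 217 in CTRL week 10 replicate 3.

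Libraries of 1 diet with 1 replicate number deviated together across weeks, with a mean correlation over the 168 miRNAs of 0.34 for 18 pairs. A difference in depth is argued against as the cause: with every library thinned to 388574 counts the mean was 0.33, and the share of relabelings within diets with as high a mean was 0.00077. Whether a batch shared by the same number in both diets is the whole cause cannot be decided. The mean over the 9 same-number pairs across diets was 0.12, lower by 0.22. This gap was just past 0.21, which combines the 95th percentiles of the spread of relabelings of both kinds and is exceeded by some of them. Such relabelings break the link by number, so they do not give the gap to be seen under a shared batch, and the spread was widened during the work. The means also differ in kind, as pairs within diets span weeks and pairs across diets share a week. The mean across diets was still higher than in most relabelings across diets (exact p = 0.019), so a shared part stays open. That replicate numbers mark ewes or fixed pools is consistent with the pattern, since the share of relabelings within diets with as high a mean was 0.00077, the smallest they can give.

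CTRL week 7 replicate 1 and CTRL week 14 replicate 3 held 826000 and 768000 CPM of miR-16b after TMM scaling, where the other 16 libraries held 358000 to 577000, and 332000 and 235000 CPM of unnamed miRNA 1, where the others held 73400 to 169000. A lower depth of both libraries is argued against, since their totals ranked 7 and 15 of 18 from the lowest, in the order named. More RNA from red blood cells may account for the pattern and stays open. miR-25 was higher in both (2520 and 1900 CPM, others 993 to 1590). miR-106b was above the others in CTRL week 7 replicate 1 alone (287 and 185 CPM, others 79.8 to 259), so 3 of 4 values exceeded all others. The list had 3 measured members, 2 of them also on the miR-17/92 list, and miR-451, miR-486 and miR-144 were not among the named features. These CPM were divided by the low TMM factors that singled out the 2 libraries, which raised every miRNA in them. Part of the excess follows from that choice, so the 3 of 4 values cannot decide the question. miR-21 (732 and 904 CPM, others 711 to 1430) and miR-191 (31300 and 32500 CPM, others 23300 to 54900) of the platelet list stayed within the range of the others. Both libraries are CTRL, and without them the difference of the red blood cell list between diets went from -0.27 to -0.11 on the log2 scale.

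Other divisions of the same libraries were compared by the number of miRNAs at an unadjusted p under 0.05. For the diet difference averaged over weeks, 10 of 100 divisions within weeks gave at least the real 19, with up to 31 in another, so chance cannot be excluded. For the interaction, 61 of 100 gave at least the real 7, up to 25, so chance cannot be excluded there either. With the libraries of a replicate number kept together, 4 of 10 divisions gave at least the real 19, up to 28. In edgeR calls, where the real divisions gave 0, 4 other divisions for the averaged difference gave any (up to 2), 6 for the interaction (up to 7) and 3 of 9 with replicate numbers kept together (up to 6). The last go with the differences between replicate numbers given above. Of the comparisons of 3 libraries against 3, those of the diets had no other division with a call, CTRL weeks 10 and 14 against week 7 had 1 and 2 (up to 1 call each), and OBESE weeks 10 and 14 had 1 each (up to 2). Keeping replicate numbers together and the comparisons of 3 libraries against 3 allow 10 divisions each, too few for a share under 0.05. Divisions with at least the real number were 5 for the diets at week 7 (real 9, highest other 19), 3 at week 10 (11 and 17) and 1 at week 14 (13 and 12). They were 8 and 9 for CTRL weeks 10 and 14 against week 7 (3 and 23, 6 and 23), and 6 and 1 for OBESE weeks 10 and 14 against week 7 (7 and 20, 13 and 12).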
